A study of Arabidopsis thaliana with 12 samples.

How the data were processed

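RNA was extracted with TRIzol from mature leaves of plants grown on soil at 22 °C in 12 hours of light and 12 of dark, per the labels' protocols, then amplified with the MessageAmp Premier kit, labelled with biotin and hybridised to Affymetrix ATH1 arrays. The 12 arrays cover 2 genotypes (wild-type Col-0 and the CPR5-C line) and 2 sprays (water and 50 µM dexamethasone), with 3 replicates in each of the 4 groups, which the labels call biological. Groups and replicate numbers were taken from the sample labels.

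The deposited values are on a log2 scale. They were made with RMA, per the submitters' processing notes; the version and settings are not given in the sources used here. The log base is not stated in the deposited file; log2 is what RMA gives, and spans of up to 9.28 for a single probe set leave no room for log10. Tested on the file, the median over the 12 arrays was 0 for every one of the 22810 probe sets (0 beyond a tolerance of 1e-06), so the authors had centred each probe set. Differences between groups are unaffected by such centring, while absolute levels, detection calls and the brightness of a probe set were not analysed here. The median of each array's centred values lay between -0.01 and 0.01. No array scanner files were used here, so the background correction and the normalization within RMA could not be varied.

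Probe sets were named from a platform annotation table, with symbols updated through gene identifiers in a table of the TAIR10.1 assembly, whose coordinates were not used. After 64 control probe sets had been left out, 22746 were tested. Of these 13513 had a single gene, 503 had several and 8730 had none in the table; 13484 of the single-gene probe sets were matched to a locus, and none was named from a probe set with several genes. Unnamed probe sets were among the largest changes, as 11 of the 20 largest rises and 14 of the 20 largest falls in CPR5-C plants; the largest of these changed by 9.03 and -4.88.

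The following choices were made before the data were examined: the groups, the 5 comparisons and their tests, the alternatives other than those named below, the rule for naming genes and 23 gene lists with 429 loci in all. The comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options) on all 12 arrays with a mean per group, which gave 8 residual and 5.79 prior degrees of freedom. P-values were two-sided and adjusted by Benjamini-Hochberg within each comparison, and a probe set was called at adjusted p under 0.05. The count that also changed by at least 1 on the log2 scale is given beside it. Figures were drawn with matplotlib 3.10.9.

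Gene lists were tested with camera at a preset correlation of 0.01 among probe sets with a single gene, adjusted over the lists tested. Of the 429 loci 70 were measured by a named probe set. The lists of intracellular immune receptors, of camalexin and tryptophan synthesis and of epidermis markers had none, 8 lists had 1 or 2 measured members and were counted but not tested, and 12 with at least 3 were tested. That minimum of 3 was set after the values were seen. Each list count is given over all probe sets and, where it differs, adjusted over the list alone. With a correlation estimated for each list, none of the list calls held (0 in each of the 5 comparisons), and each p is given beside the call in the report.

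Named genes followed a fixed rule: the 10 largest rises and 10 largest falls for the dexamethasone effect in CPR5-C plants and for the interaction, and 5 of each for the other comparisons, among called probe sets with a single gene and, for comparisons of 2 groups, without overlap between their arrays. To these came up to 4 members of each list with the smallest p in each comparison. This gave 330 gene results over the 5 comparisons; the text leaves out some that did not pass the threshold, and every alternative was computed for all of them. CPR5 and the defence genes PR1, PR2, PR5, ICS1, PAD4, EDS1 and WRKY70 were to be named wherever measured and are not reported here, since no probe set was named for them.

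The alternatives fixed in advance were the replicate number as a fixed or random block, the arrays of only the groups compared, quantile normalization, cyclic loess normalization, centring of each array on its median, a trended and robust variance model, array weights, other thresholds, an estimated correlation in camera, fry in place of camera, Spearman's rho and each array left out in turn. Added after the data had been seen were scaling each array to the mean of its poly-A spike controls (leaving out the TrpnX probe sets), a fit without the 3 wild-type water arrays, and a fit on single-gene probe sets alone. The sets of organelle genes, the gene families, the classes of control probe sets the simulation of normalization on centred values and the test with each wild-type water array held out were chosen after the data had been seen as well.

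The fit was tested on simulated arrays of 22746 probe sets with 50 changed at each size. For the dexamethasone effect in CPR5-C plants 18.0%, 84.0%, 100% and 98.0% were recovered at log2 changes of 0.25, 0.5, 1 and 2. For the interaction 0%, 30.0%, 94.0% and 98.0% were recovered, and for the genotypes after dexamethasone 14.0%, 68.0%, 100% and 98.0%. Far fewer probe sets changed in these arrays than the 10895 called for dexamethasone in CPR5-C plants. The Benjamini-Hochberg adjustment is looser with more changes, so these shares do not give the recovery in the real fit. Camera recovered 3 of 3 lists raised by 0.5 and called 0 others. The simulated probe sets varied independently, whereas the estimated correlation was 0.10 for the light reaction list and 0.30 for chlorophyll synthesis. The run therefore cannot show how often lists are called falsely in these data. Values of single control measures were compared with exact two-sided permutation tests, for which 3 arrays against 3 allow no p below 0.1.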

Results

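Transcript levels were measured in mature leaves of 4-week-old Arabidopsis thaliana plants on 12 ATH1 microarrays, each hybridised with RNA of a single sample. The plants were wild-type Col-0 or a Col-0 line, here called CPR5-C, that carries the C-terminal part of CPR5 fused to YFP behind a promoter switched on by dexamethasone, a synthetic glucocorticoid. CPR5 is a membrane protein of the nuclear pore whose loss is known to give spontaneous lesions, raised immunity and early senescence. According to the study's design, this part disturbs the native protein and acts as a dominant negative. Leaves were sprayed with water or 50 µM dexamethasone and collected 24 hours later, which gave 4 groups of 3 biological replicates. The deposited values are log2 signals from which the median over the 12 arrays had been subtracted for each probe set, so they show differences between groups and no absolute level. The number of arrays limits the precision, and all log2 changes below have the fitted standard error (SE) from 3 arrays per group. The SD of the centred values over all probe sets was 0.68 to 0.69 on the CPR5-C dexamethasone arrays and 0.13 to 0.23 on the other 9. CPR5 itself was not analysed here, since no probe set was named for it, so the induction of the transgene was not checked.

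The main comparison asked what changes in leaves once the CPR5 fragment is induced. Dexamethasone raised BGLU45, a beta-glucosidase, 347-fold in CPR5-C plants (log2 change 8.44, SE 0.08). The cell wall enzyme XTH19 rose 88.0-fold (6.46, SE 0.21), the senescence-associated sugar transporter SAG29 rose 85.4-fold (6.42, SE 0.14), and the dehydrin LTI30 rose 40.7-fold (5.35, SE 0.20). The other largest rises of named genes were AT4G23680 (6.96), AT2G36220 (6.42), AT1G64405 (6.37), AT5G10120 (6.12), AT5G39520 (5.48) and AT5G47060 (5.13). The largest falls of named genes were AT5G48490 (-5.34, SE 0.35), AT1G13650 (-5.11, SE 0.35) and BCAT4, an enzyme of methionine-derived glucosinolate synthesis, which was 18.8-fold lower (-4.24, SE 0.46). STOMAGEN, a peptide that promotes stomatal formation, was 12.9-fold lower (-3.69, SE 0.25). The other large falls were AT5G03350 (-4.17), AT1G23390 (-4.07), AT1G60590 (-3.92), AT3G06070 (-3.64), AT5G57340 (-3.48) and AT5G61590 (-3.46).

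Among the immune lists in CPR5-C plants after dexamethasone, 2 of 4 measured genes of salicylic acid and N-hydroxypipecolic acid synthesis and signalling rose, AT5G52810 (SARD4, 0.97) and SAG101 (0.77), while UGT76B1 (0.65, limma adjusted p = 0.104) and BSMT1 (0.23, adjusted p = 0.151) did not pass the test. Of the 2 salicylic-acid-responsive markers, WRKY53 fell (-0.50) and GRX480 did not pass (-0.24, adjusted p = 0.207). In pattern-triggered immunity, the kinase BIK1 rose 3.19-fold (1.67), WRKY22 fell (-0.79) and the receptor EFR was at 0.07 (adjusted p = 0.582). Of 4 genes of endoplasmic reticulum chaperones and secretion, the transcription factors BZIP28 (0.70) and BZIP60 (0.62) and the calreticulin CRT1b (0.51) rose, and ATERDJ3B was at 0.00 (adjusted p = 0.997). The jasmonate list had 2 falls in 3 genes, the jasmonate methyltransferase JMT (-2.48) and the thionin THI2.1 (-0.41), and PDF1.2 did not pass (1.1, SE 0.58, adjusted p = 0.144). With an array left out PDF1.2 ranged from 0.061, without CPR5-C dexamethasone replicate 3, to 1.75, called without replicate 2. None of these lists shifted as a whole by camera, with adjusted p = 0.0947 for salicylic acid synthesis, 0.0696 for the endoplasmic reticulum, 0.649 for pattern-triggered immunity and 0.181 for jasmonate; the salicylic acid markers were too few to test. Both measured genes of aliphatic glucosinolate synthesis fell, BCAT4 and AT2G31790 (UGT74C1, -2.01), and the single ethylene gene, EIN3, was at 0.12 (adjusted p = 0.186).

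Among the stress, cell cycle and growth lists, both measured abscisic acid response genes rose in CPR5-C plants, COR15A 20.8-fold (4.38, SE 0.15) and COR47 by 3.71 on the log2 scale (SE 0.11). In the senescence and cell death list SAG29 and WRKY6 (0.54) rose while WRKY53 fell, with adjusted p = 0.167 for the list. Scaled to the poly-A spikes this was the 1 list called in CPR5-C plants (mean 2.57 in place of 2.15, camera, adjusted p = 0.00021). Of the oxidative stress genes the zinc finger factor STZ fell (-0.56), while UGT73B5 (0.19, adjusted p = 0.110) and GSTU25 (0.02, adjusted p = 0.865) did not pass, and the list had adjusted p = 0.992. Of the heat shock genes HSA32 (-0.26) and AT5G48570 (FKBP65, -0.68) fell and AT1G53540 was at 0.17 (adjusted p = 0.209), with adjusted p = 0.618 for the list. The cyclin-dependent kinase inhibitor SIM rose (0.65) and PRL, a subunit of the replicative helicase, fell (-0.51). In the auxin and cell expansion list IAA29 rose 10.8-fold (3.43), the expansin EXPA8 was 8.85-fold lower (-3.15) and GH3.3 was at -0.06 (adjusted p = 0.592), and the list had adjusted p = 0.992. The clock gene GI rose 5.29-fold (2.40, SE 0.10). For cell types, both guard cell markers fell, AT1G22690 (GASA9, -3.06) and the guard cell regulator FMA (-0.28), and the phloem transporter SWEET11 rose (0.51). The SE of the list genes named for this comparison lay between 0.05 and 0.58.

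On the deposited scale most measured photosynthesis genes were lower in CPR5-C plants after dexamethasone. All 7 measured genes of the light reactions were lower, among them PSBY (-0.67), the antenna gene LHCB4.2 (-0.65), PSAN (-0.59) and the ATP synthase subunit ATPC1 (-0.37). The list shifted by a mean of -0.46 (camera, adjusted p = 0.00280), and the shift did not pass with adjusted p = 0.199 with an estimated correlation. Scaled to the poly-A spikes the mean was -0.051 and did not pass (camera, adjusted p = 0.217). In the Calvin cycle SBPASE (-0.62) and PRK (-0.39) fell and RCA was at -0.07 (adjusted p = 0.374), with adjusted p = 0.139 for the list. Of 7 chlorophyll synthesis genes 6 fell, among them CHLM (-1.49), CHLI2 (-0.94) and HEME1 (-0.50), whereas PORB, a protochlorophyllide reductase, rose (1.49), with adjusted p = 0.0696 for the list. With spike scaling the means of the Calvin cycle and chlorophyll synthesis lists were 0.052 and 0.060. Of 15 nuclear pore genes 3 rose and 2 fell, and adjusted over the list alone 3 rose and 1 fell. They included AT1G59660 (NUP98B, 0.90), AT2G41620 (NUP93A, 0.49), SEH1H (0.44) and AT3G14120 (NUP107, -0.27), and the list had adjusted p = 0.525. In the other lists the counts adjusted over the list alone were the same as those over all probe sets.

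In all, 10895 of 22746 probe sets (47.9%) differed in CPR5-C plants between dexamethasone and water (limma, adjusted p under 0.05), 5304 higher and 5591 lower. Of these, 1211 were higher and 1230 lower by at least 1 on the log2 scale. The split depended on the scaling: with each array scaled to its poly-A spike controls, the median of all probe sets moved to 0.39, and 87.8% of 15212 calls were higher in place of 48.7%. Quantile and cyclic loess normalization of the deposited values gave 5557 and 3732 calls (interaction 3538 and 1515, genotypes after dexamethasone 5110 and 3187), and cyclic loess turned the sign of many named genes; in simulated arrays with known changes, cyclic loess of values centred in this way returned a median of 4.30% of each change of at least 1. Under the spike scaling HSA32, ATPC1, PRK, RCA, AT3G14120, GH3.3 and FMA, all below 0 as deposited, lay above 0. These are the named genes with a call before or after. The scaling added 0.41 to every change, so any fall smaller than that turned. Among others this holds for the light reaction genes PSBW (-0.34 as deposited), PSAE-1 (-0.32) and LHCB4.1 (-0.31), and for GRX480 (-0.24).

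**Figure D1:**
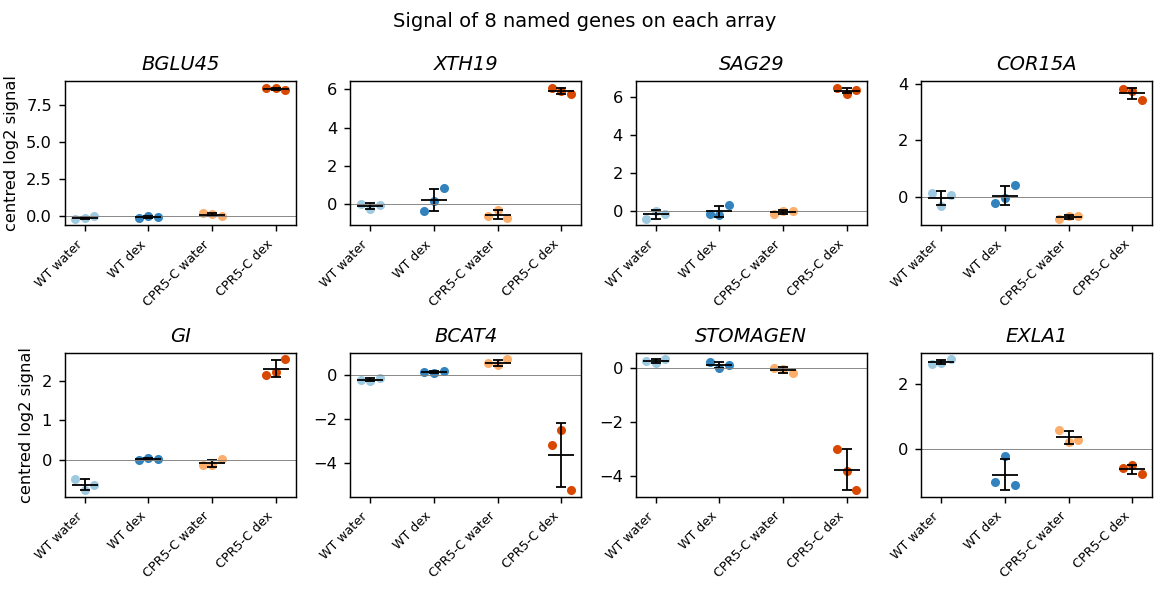
Centred log2 signal of 8 named genes (vertical axes, log2 units relative to the median of the 12 arrays) in the 4 groups of plants. Points are single arrays, and the black marks show the mean ± SD (n = 3 per group). BGLU45, XTH19, SAG29, COR15A and GI were higher, and BCAT4 and STOMAGEN lower, on the CPR5-C dexamethasone arrays. EXLA1 was highest on the wild-type water arrays. On the cyclic loess scale the changes of BGLU45 and STOMAGEN after dexamethasone changed sign in CPR5-C plants (-0.33 and 0.14). In simulated arrays loess also turned the sign of many changes in values centred in this way.

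Transcripts encoded in the organelles were grouped after their values had been seen. Of 69 probe sets for plastid-encoded genes, 50 were lower in CPR5-C plants after dexamethasone, 0 were higher, and the median change was -0.61 (range -1.58 to 0.10). The largest falls were rps16 (-1.58), rpl33 (-1.38), rps18 (-1.29) and rpoC1 (-1.25). The plastid set was taken by chromosome, but the mitochondrial set by gene symbol (nad, cox, ccb, matR and orfX). Mitochondrial genes with other symbols were not sought, so that set is partial. Of its 23 probe sets, 16 were higher and 1 lower, with a median of 0.71 (range -0.61 to 2.46). Subunits of respiratory complexes were among those that rose, with cox2 at 1.47 and nad5 at up to 1.23, whereas nad2 fell (-0.61). The gene nad1 had several probe sets, from 0.14 (not called) to 2.46, and so weighs more than other genes in the median and the test. By camera the plastid genes had p = 6.3e-11 and, with an estimated correlation, p = 0.107; the mitochondrial genes had p = 5.8e-07 and, with an estimated correlation, p = 0.0448. With the arrays scaled to the poly-A spikes the plastid median was -0.20 (22 lower, 6 higher) and the mitochondrial median 1.12. Quantile normalization gave plastid and mitochondrial medians of -0.34 (15 lower) and 0.33 (9 higher), and cyclic loess -0.11 (9 lower) and 0.0070 (0 higher, 1 lower). On simulated values centred in this way, these 2 scalings returned a median of 50.0% and 4.30% of each change of at least 1. The smaller medians under them therefore cannot weigh the organelle shifts. Copies of mitochondrial DNA in the nuclear genome were not separated from the mitochondrial genes.

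**Figure D2:**
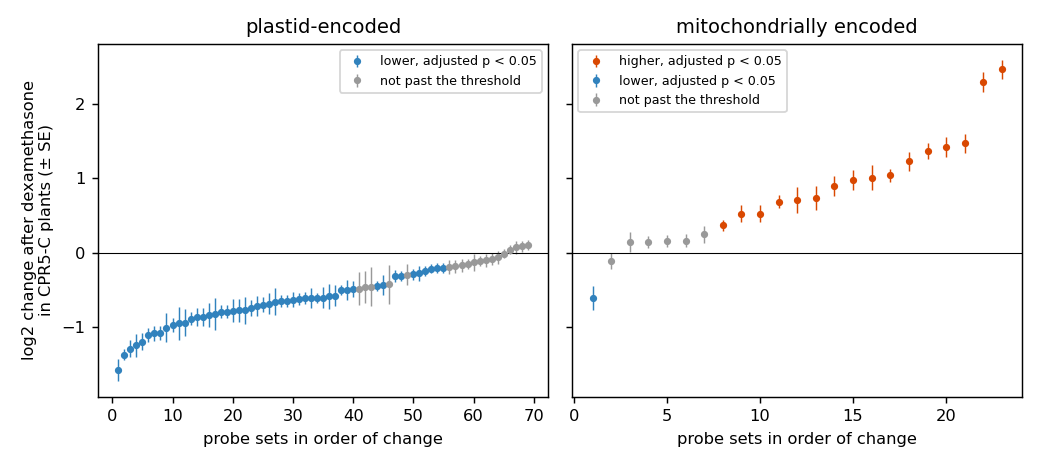
Log2 change after dexamethasone in CPR5-C plants (vertical axis, ± SE) of each probe set for plastid-encoded (left, 69) and mitochondrially encoded genes (right, 23), in order of change along the horizontal axis. Colours mark probe sets past adjusted p of 0.05. On the left 50 were lower and 0 higher; on the right 16 were higher and 1 lower. With arrays scaled to poly-A spikes 22 plastid probe sets were lower and 6 higher. With cyclic loess 0 mitochondrial probe sets were higher and 1 lower, but loess removed most of each large simulated change on centred values.

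Wild-type plants served as the control for dexamethasone itself. Among named genes, 2 genes of cell wall and cell expansion fell most: the expansin-like gene EXLA1 was 11.1-fold lower after dexamethasone (-3.47, SE 0.18) and EXO, which acts in cell expansion, 9.10-fold lower (-3.19, SE 0.15). AT2G27080 (-3.01), AT1G33760 (-3.01) and AT1G77640 (-2.84) followed. The rises were smaller, with AT1G20070 at 1.74 (SE 0.12), AT1G11700 at 1.35, AT1G79160 at 1.15, the sugar transporter SWEET13 at 1.1 (2.15-fold, SE 0.09) and AT2G44940 at 1.07. PORB was 2.18-fold lower (-1.13, SE 0.11), and the chlorophyll synthesis list shifted down by a mean of -0.30 (camera, adjusted p = 0.00173, but adjusted p = 0.380 with an estimated correlation). PORB was the only called member of 7, while adjusted over the list alone 5 were lower; HEME1 (-0.23, adjusted p = 0.0713), HEME2 (-0.22, adjusted p = 0.111) and CHLI2 (-0.19, adjusted p = 0.155) did not pass over all probe sets.

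The immune transcription factors WRKY53 (-1.87, 3.65-fold, SE 0.14) and WRKY22 (-1.17) and the zinc finger factor STZ (-1.24) also fell in wild-type plants after dexamethasone, as did COR47 (-0.46) and AT1G22690 (-0.61). AT2G31790 (0.39), JMT (0.53), GI (0.65) and the nuclear pore gene AT1G73240 (NDC1, 0.39) rose. No member passed in the lists of salicylic acid synthesis, endoplasmic reticulum, cell cycle, ethylene, heat shock, light reactions, Calvin cycle, auxin and cell expansion or vascular markers. The values there ran from IAA29 (-0.62, adjusted p = 0.0560) and EXPA8 (-0.44, adjusted p = 0.213) to AT5G48570 (0.46, adjusted p = 0.258). NUP1, a nuclear pore gene, was at 0.32 (adjusted p = 0.0527), SAG29 at 0.15 (adjusted p = 0.580), COR15A at 0.09 (adjusted p = 0.801) and PDF1.2 at 0.81 (adjusted p = 0.487). Adjusted over the list alone, 1 heat shock, 1 auxin and 1 more nuclear pore gene and SWEET11 (0.16, adjusted p = 0.161 over all) also passed. Beside chlorophyll synthesis no list shifted by camera, the lowest adjusted p being 0.109 for senescence and cell death. In all 2065 probe sets differed, 1154 higher and 911 lower, of which 33 and 172 by at least 1. Of these, 1076 also differed in the same direction between CPR5-C water and wild-type water plants, a comparison with the same wild-type water arrays. Scaled to the poly-A spikes, 13.3% of 987 calls were higher in place of 55.9%, with the median of all probe sets at -0.17.

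The 2 dexamethasone responses were then set side by side. Of 1610 probe sets called in both genotypes (989 expected if independent), 1065 (66.1%) changed in the same direction. In both genotypes 504 were higher (269 expected) and 561 lower (224 expected). In opposite directions, 368 were lower in CPR5-C and higher in wild-type plants (284 expected) and 177 the other way round (212 expected). Across probe sets, which are not independent replicates, the changes had Pearson r = 0.208 and Spearman rho = 0.154. The changes themselves shared no array, but the calls of both genotypes used the same fitted spread of each probe set. A probe set with a low spread is called more readily in both genotypes. Part of the excess over the expected counts may come from this.

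The genotype by dexamethasone interaction tested whether the response differed between CPR5-C and wild-type plants. BGLU45 (8.41, SE 0.11), SAG29 (6.26, SE 0.19), XTH19 (6.15, SE 0.30) and LTI30 (5.53, SE 0.28) responded more strongly in CPR5-C plants, as did AT4G23680 (6.68), AT2G36220 (6.59), AT1G64405 (6.43), AT5G10120 (6.11), AT5G39520 (5.46) and AT5G50915 (5.34). BCAT4 (-4.60, SE 0.65), the sugar transporter SWEET13 (-3.94, SE 0.13), the beta-glucosidase BGLU47 (-3.65, SE 0.18) and STOMAGEN (-3.56, SE 0.35) had the opposite sign, with AT1G13650 (-4.69), AT1G68600 (-4.46), AT1G60590 (-4.30), AT5G48490 (-3.90), AT5G03350 (-3.60) and AT3G26960 (-3.48). All 3 genes of the senescence and cell death list had higher responses in CPR5-C plants, SAG29, WRKY53 (1.37) and WRKY6 (0.75), with a list mean of 2.79 (camera, adjusted p = 0.00289, but adjusted p = 0.115 with an estimated correlation). WRKY53 fell in both genotypes and fell less in CPR5-C plants. All 7 light reaction genes had lower responses, among them PSBY (-0.64), LHCB4.2 (-0.59), PSAN (-0.58) and ATPC1 (-0.36), with a list mean of -0.44 (camera, adjusted p = 0.00289, but adjusted p = 0.115 with an estimated correlation).

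In the other lists the interaction was positive for COR15A (4.29), COR47 (4.17), IAA29 (4.05), PORB (2.62), GI (1.75), BIK1 (1.62), AT5G52810 (0.85), BZIP60 (0.79), SAG101 (0.78), AT1G59660 (0.73), SIM (0.70), BZIP28 (0.57), CRT1b (0.52) and SWEET11 (0.35). It was negative for JMT (-3.01), EXPA8 (-2.70), AT1G22690 (-2.45), AT2G31790 (-2.40), CHLM (-1.34), AT5G48570 (-1.14), CHLI2 (-0.75), SBPASE (-0.63), THI2.1 (-0.42), PRK (-0.41), FMA (-0.35) and HEME1 (-0.27). The difference did not pass for PRL (-0.44, adjusted p = 0.0553), STZ (0.68, adjusted p = 0.0775), WRKY22 (0.37, adjusted p = 0.173), AT2G41620 (0.43, adjusted p = 0.0546), NUP1 (-0.31, adjusted p = 0.0908), UGT76B1 (0.58, adjusted p = 0.346) or PDF1.2 (0.30, adjusted p = 0.821). PDF1.2 depended on 1 array: without CPR5-C dexamethasone replicate 3 its interaction was -0.74 and called. Adjusted over the list alone, PRL and 1 more chlorophyll synthesis gene passed as well. For all other lists tested, camera gave adjusted p of 0.119 or more. In all 8755 probe sets had an interaction, 4121 positive and 4634 negative, of which 1180 and 1183 by at least 1. Of these, 7005 were called in CPR5-C plants and not in wild-type plants, and 545 were called in both with opposite direction. The interaction contains the wild-type water arrays, so a deviation of those plants would enter it too. Scaled to the poly-A spikes, 93.3% of 15511 calls were positive in place of 47.1%, the median of all probe sets moved to 0.59, and the light reaction mean turned to 0.14.

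The genotypes were compared after water to see whether the uninduced line already differed from wild type. Of the 1610 probe sets that differed, 1076 moved the same way in wild-type plants after dexamethasone, against the same wild-type water arrays. CPR5-C water and wild-type dexamethasone plants differed at 344. In what follows, a deviation of the wild-type water plants can therefore not be told apart from a difference of the line. Among named genes EXLA1 was 5.01-fold lower in CPR5-C plants (-2.32, SE 0.18) and EXO 4.56-fold lower (-2.19, SE 0.15), followed by AT1G50040 (-2.16), AT1G33760 (-2.07) and AT1G77640 (-1.97). The largest rises of named genes were AT1G68600, 2.69-fold (1.43, SE 0.21), AT3G15650 (1.34), AT5G11930 (1.33), AT3G49160 (1.18) and AT1G76960 (1.08). Of 7 measured chlorophyll synthesis genes 3 were lower (PORB at -0.73, CHLI2 at -0.49 and HEME2 at -0.29) and 4 did not pass, among them CHLM at -0.20 (adjusted p = 0.0619); adjusted over the list alone 6 were lower. The list mean was -0.31 (camera, adjusted p = 4.6e-06, but adjusted p = 0.171 with an estimated correlation). WRKY22 (-0.68) and COR15A (-0.66) were lower, and GI (0.55), AT2G31790 (0.52) and NUP1 (0.35) higher. The lists without a called member here were those of salicylic acid, jasmonate, ethylene, senescence, oxidative stress, heat shock, endoplasmic reticulum, cell cycle, light reactions, Calvin cycle, auxin, guard cells and vascular tissue. Below the threshold stayed WRKY53 at -0.44 (adjusted p = 0.0798), JMT at 0.28 (adjusted p = 0.0923), AT5G48570 at 0.68 (adjusted p = 0.0903), AT3G16310 at -0.28 (adjusted p = 0.0619), SAG29 at 0.14 (adjusted p = 0.666) and BCAT4 at 0.78 (adjusted p = 0.392). The other lists tested had camera adjusted p of 0.480 or more. Adjusted over the list alone, WRKY53, JMT, COR47 (-0.31, adjusted p = 0.134 over all), AT5G48570, AT3G16310, AT1G22690 (-0.38, adjusted p = 0.0677 over all) and FMA (0.20, adjusted p = 0.183 over all) also passed.

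In all 1610 probe sets differed between the water groups, 967 higher in CPR5-C plants and 643 lower, of which 23 and 67 by at least 1. The count was 922 without CPR5-C water replicate 2, 900 without CPR5-C water replicate 3 and 1019 without wild-type water replicate 3. Scaled to the poly-A spikes, 34.0% of 462 calls were higher in place of 60.1%.

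After dexamethasone, when both genotypes had the same treatment, BGLU45 was 393-fold higher in CPR5-C plants (8.62, SE 0.08) and SAG29 84.4-fold higher (6.40, SE 0.14), with AT4G23680 at 6.79, AT1G64405 at 6.39 and AT2G36220 at 6.25. STOMAGEN was lower (-3.88, SE 0.25), as were AT1G13650 (-4.97), AT5G48490 (-4.79), AT1G60590 (-4.06) and AT5G03350 (-3.93). All 3 senescence and cell death genes were higher, SAG29, WRKY53 (0.94) and WRKY6 (0.71) (camera, adjusted p = 0.00919, but adjusted p = 0.162 with an estimated correlation). All 7 light reaction genes were lower, among them LHCB4.2 (-0.66), PSBY (-0.60), PSAN (-0.59) and ATPC1 (-0.41) (camera, adjusted p = 0.00173, but adjusted p = 0.162 with an estimated correlation). Of the chlorophyll synthesis genes 6 were lower, among them CHLM (-1.54), CHLI2 (-1.24) and HEME2 (-0.55), and PORB was higher (1.89) (camera, adjusted p = 0.0300, but adjusted p = 0.266 with an estimated correlation).

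Other list genes higher in CPR5-C than in wild-type plants after dexamethasone were COR47 (3.86), COR15A (3.62), IAA29 (3.62), GI (2.30), BIK1 (1.71), AT1G59660 (0.93), AT5G52810 (0.86), SIM (0.83), SAG101 (0.74), BZIP28 (0.70), BZIP60 (0.68), CRT1b (0.58), STZ (0.58), SWEET11 (0.33), UGT73B5 (0.31) and SEH1H (0.29). Lower were BCAT4 (-3.81), EXPA8 (-3.15), AT1G22690 (-2.83), JMT (-2.73), AT2G31790 (-1.88), SBPASE (-0.68), PRL (-0.62), PRK (-0.40), THI2.1 (-0.36), AT3G14120 (-0.23), AT4G32910 (NUP85, -0.22) and HSA32 (-0.19). AT1G53540 (0.26, adjusted p = 0.0570), EIN3 (0.16, adjusted p = 0.0786), WRKY22 (-0.31, adjusted p = 0.0870), FMA (-0.15, adjusted p = 0.172) and PDF1.2 (0.22, adjusted p = 0.802) did not pass. PDF1.2 was at -0.82 and called without CPR5-C dexamethasone replicate 3. Adjusted over the list alone EIN3 and AT1G53540 passed as well, and 1 nuclear pore gene was lower in place of 2. The other lists tested had camera adjusted p of 0.0896 or more. In all 10786 probe sets differed, 5308 higher and 5478 lower, of which 1193 and 1163 by at least 1. Scaled to the poly-A spikes, 91.7% of 18423 calls were higher in place of 49.2%, the median of all probe sets moved to 0.53, and the means of the light reaction and chlorophyll synthesis lists turned to 0.06 and 0.15.

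**Figure D3:**
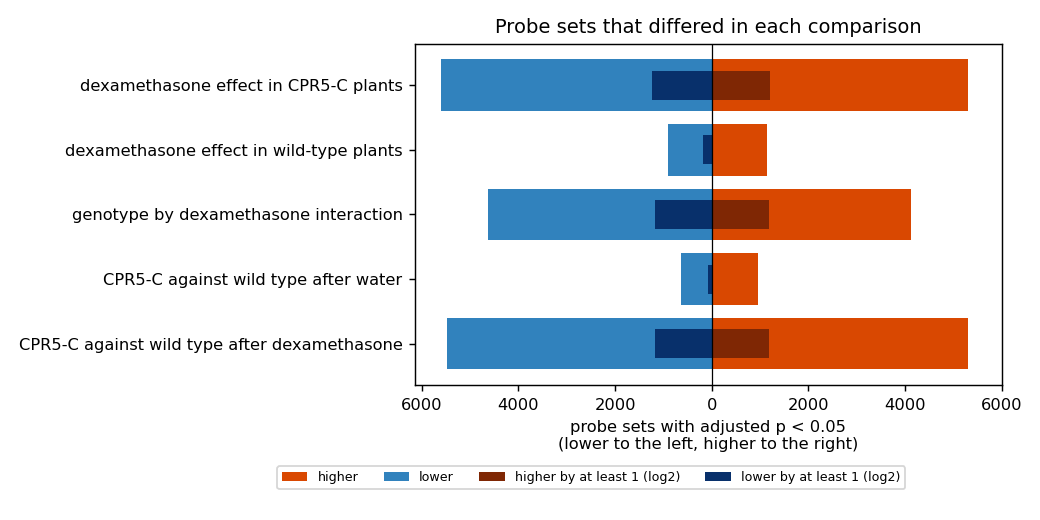
Number of probe sets past adjusted p of 0.05 in each of the 5 comparisons (horizontal axis, lower to the left of 0 and higher to the right), of 22746 tested. Dark bars count those that also changed by at least 1 on the log2 scale. The 3 comparisons that involve the CPR5-C dexamethasone arrays had 8755 to 10895 calls, and the other 2 had 1610 and 2065. With the arrays scaled to poly-A spikes 87.8% of the calls in CPR5-C plants were higher in place of 48.7%.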

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

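Of the tests below, the test of dexamethasone alone with a wild-type water array held out, the test of RNA degradation, the control probe set classes, the simulation of centred values and the spike scaling were chosen after the result was seen.

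Genes that rose in a genotype and fell in the other stood out because the interaction tested the difference itself. The interaction covered 8755 probe sets, the senescence and cell death list with a mean of 2.79 and the light reaction list with -0.44. With an estimated correlation in camera 0 lists were called. Scaled to the poly-A spikes the senescence mean was 3.38 and the light reaction mean turned to 0.14. Of the 100 splits of the arrays drawn for the interaction, 1 gave as many calls, the real one, and the highest other split gave 8346. The counts follow a structure of the samples: the 10 splits that kept the 3 CPR5-C dexamethasone arrays together gave 7699 to 8755 calls, and those that parted them at most 20. Only 20 of the 200 possible splits keep them together, too few for a share under 0.05.

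The following genes rose in response to dexamethasone in CPR5-C plants and fell in wild-type plants. AT5G50915 changed by 4.27 and -1.07 (interaction 5.34). COR47, a dehydrin, changed by 3.71 and -0.46 (interaction 4.17). PORB, which reduces protochlorophyllide, changed by 1.49 and -1.13 (interaction 2.62). The following fell in CPR5-C and rose in wild-type plants. AT1G68600 changed by -3.45 and 1.01 (interaction -4.46), and the sugar transporter SWEET13 by -2.84 and 1.1 (interaction -3.94). AT1G76960 changed by -2.32 and 0.99 (interaction -3.31), AT1G11700 by -1.94 and 1.35 (interaction -3.29), and the jasmonate methyltransferase JMT by -2.48 and 0.53 (interaction -3.01). AT5G11930 changed by -1.86 and 1.0 (interaction -2.87), the glucosinolate gene AT2G31790 by -2.01 and 0.39 (interaction -2.40), and AT2G44940 by -0.35 and 1.07 (interaction -1.41). Of these 11 genes 9 were also called between CPR5-C water and wild-type water plants, in the direction of their wild-type response. AT1G68600 was at 1.43 there, AT5G11930 at 1.33, AT1G76960 at 1.08, AT1G11700 at 1.02, SWEET13 at 0.65, AT2G31790 at 0.52, AT2G44940 at 0.47, PORB at -0.73 and AT5G50915 at -1.07. The wild-type response and this difference use the same wild-type water arrays, so they share chance values, and no value free of that was computed for these genes.

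Control probe sets, which enter no comparison of genes, differed as well. The housekeeping controls were at 0.35 on the CPR5-C dexamethasone arrays and 0.01 on the CPR5-C water arrays, a difference of 0.34 (SE 0.03, exact permutation p = 0.1, the smallest possible). The poly-A spikes, transcripts that are usually added to RNA before labelling, differed by -0.41 (SE 0.15, exact permutation p = 0.1), and by -0.37 with the TrpnX probe sets included. Whether the spike signal lay above background cannot be told from the centred values, which limits every result scaled to the spikes. The hybridization controls differed by -0.15 (SE 0.06, exact permutation p = 0.1), and the spikes relative to them by -0.27 (SE 0.20, exact permutation p = 0.4).

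The extent of the response in CPR5-C plants, 10895 probe sets, was weighed against the normalization between arrays and RNA degradation. Degradation is argued against by the 3' minus 5' signal of actin and GAPDH, which differed by -0.050 (SE 0.06, exact permutation p = 0.6) where it would have to rise. The normalization stays open: the fewest calls under another scaling were 3732, with cyclic loess, and the bound set beforehand would have counted this for it. That reading was changed after the value was seen, on a simulation in which cyclic loess returned a median of 4.30% of each change on centred values (652 of 2442 called with their sign) and 99.9% on uncentred values (2436 of 2442); quantile normalization returned 50.0% (2228 with their sign) and 98.3%. Whether a true rise of total transcripts hides in the deposited scale cannot be told. Spike scaling gave 15212 calls with 87.8% higher, but these follow from 1 constant (0.41) added to every change. On the 3 CPR5-C dexamethasone arrays the spikes lay at -0.46, -0.59 and -0.09. The CPR5-C water arrays had 0.08, 0.07 and -0.05, so dexamethasone replicate 3 hardly showed the shift.

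Against the wild-type water plants, the wild-type dexamethasone and CPR5-C water plants moved alike: 1077 probe sets were called in both, 1076 in the same direction (609 higher, 49.1 expected if independent; 467 lower, 25.8 expected), and the changes had r = 0.785 (0.50 with unchanged groups on shared arrays). Noise of the shared arrays that is independent between probe sets is argued against by the covariance of 0.0369. The highest of 100 simulations was 0.00554 (mean 0.00520, difference 0.0317). Noise common to many probe sets was not simulated, so the simulation cannot argue against it. Residuals of arrays in different groups correlated at up to r = 0.42. A single deviating array is argued against by the 823, 777 and 700 shared calls kept without wild-type water replicate 1, 2 and 3. Still, 3 arrays cannot be split, and part of the excess may come from them. Dexamethasone as the whole cause is argued against for the probe sets at least 1 lower in wild-type plants after dexamethasone. These were chosen without 1 wild-type water array and measured against it. CPR5-C water plants, which had no dexamethasone, lay at medians of -0.83, -0.75 and -0.91 there (SE over arrays 0.07). The 609 shared higher calls and the smaller falls were not tested in this way. Dexamethasone in CPR5-C plants changed the 172 chosen on all arrays by a further median of -1.02, so a part for it stays open. A difference in handling, harvest or growth of the wild-type water plants cannot be told apart from biology here, because a single group carries it; CPR5-C water and wild-type dexamethasone plants differed at 344 probe sets (253 higher, 91 lower), fewer than either against wild-type water. The probe sets called in both against wild-type water include EXLA1 and EXO, so the wild-type dexamethasone effect may partly reflect the wild-type water plants. The interaction contains that effect, so its 8755 calls, with the 545 called in opposite directions, may partly reflect them too.

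For the comparisons of 3 arrays against 3, the 10 splits are too few for a share under 0.05. In each the real split was 1 of the 10 with as many calls (10895 for dexamethasone in CPR5-C plants, 2065 in wild-type plants, 1610 between genotypes after water and 10786 after dexamethasone), and the highest other split gave 0 calls.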

How the results depend on the processing

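The spike scaling, the fit without the wild-type water arrays, the single-gene fit and the simulation are tests chosen after the result was seen; all others were planned. Comparisons are given in the order dexamethasone in CPR5-C plants, dexamethasone in wild-type plants, interaction, genotypes after water and genotypes after dexamethasone. The counts of calls stayed within 1.5 times the reported ones, for all 5, under the 2 forms of replicate block, group-wise fits (4 comparisons), median centring, trended and robust variance, and array weights; for the first and last also without the wild-type water arrays. The fixed replicate block gave 10671, 1852, 8487, 1352 and 10558 calls and changed no list count; of named genes it ended 3 calls and added 2. The numbers did not pair the arrays: 2 of 18 same-number pairs correlated above 0.1 (r -0.21 to 0.36) and 3 of 12 arrays matched their own number best. Across groups the highest r was 0.42, for wild-type water replicate 2 with wild-type dexamethasone replicate 3, which differ in number. A block that the numbers do not follow stays possible and was not modelled. Leaving out an array gave 10085 to 11131, 1466 to 2133, 8087 to 8747, 900 to 1665 and 9913 to 11048 calls, list calls of 1 to 1, 1 to 3, 2 to 3, 1 to 1 and 3 to 4, and an agreement r of 0.175 to 0.241. Counts that also changed by at least 1 were 2441, 205, 2363, 90 and 2356, and at adjusted p under 0.01 those of dexamethasone in wild-type plants and of the genotypes after water were 1152 and 783, fewer by construction. On single-gene probe sets, fewer by construction, counts were 5798, 1012, 4555, 708 and 5744. Quantile normalization gave 5557, 3538 and 5110 for dexamethasone in CPR5-C plants, the interaction and the genotypes after dexamethasone, and cyclic loess 3732, 1515 and 3187 with r at 0.362 and 39.4% of the interaction calls positive. On simulated centred arrays, with 12040 calls before scaling, quantile normalization returned a median of 50.0% of each change of at least 1 (7051 calls) and cyclic loess 4.30% (5890 calls). Spike scaling gave 987, 15511, 462 and 18423 for all but the first comparison, in that order. By construction it added the same constant to every change of a comparison (0.41, -0.17, 0.58, -0.064 and 0.52). It also brought the spread of the spikes between arrays into every probe set. For dexamethasone in CPR5-C plants the SE of ATPC1 was 0.16 in place of 0.055, and that of PRK 0.16 in place of 0.057. How much the spread and the constant each lowered the counts was not tested. List calls were 0, 0, 0, 0 and 0 with an estimated correlation and 8, 3, 9, 2 and 9 with fry, which tests another hypothesis. In wild-type plants they were 2 in the group-wise fit, 2 with quantile, 6 with spikes, 2 without CPR5-C dexamethasone replicate 3 and 3 without wild-type dexamethasone replicate 3; after water 2 with spikes; the spikes also added jasmonate in the interaction (-0.46) and between genotypes after dexamethasone (-0.43); and with loess 0 in CPR5-C plants and 1 for the last comparison. For these the cause was not tested. Of 330 named gene results 197 were called; 56 of these kept their call and direction under every alternative, 140 did not pass under at least 1, and BGLU45 in CPR5-C plants passed under all but turned sign with loess. The sign turned under at least 1 for 147 of the 330, and for 79 of these with a call before or after. All of these counts include quantile and loess normalization of the centred values, and no count without them was made. In the simulation loess called 652 of 2442 changes of at least 1 with their sign. The counts therefore say little of how firm the named results are. Under the fixed and random replicate block 325 and 327 of the 330 results had the same outcome. Unless said otherwise, the signs listed next are of genes and lists with a call before or after.

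Under cyclic loess the sign turned for dexamethasone in CPR5-C plants in the light reaction list (0.093), BGLU45 (-0.33), AT4G23680 (-0.027), AT5G10120 (-0.23), AT5G39520 (-0.044), LTI30 (-0.043), AT1G13650 (0.13), STOMAGEN (0.14), BZIP28 (-0.075), BZIP60 (-0.10), CRT1b (-0.023), SIM (-0.12), BIK1 (-0.086), LHCB4.2 (0.11), PSBY (0.11), PSAN (0.15), ATPC1 (0.14), SBPASE (0.15), PRK (0.042), CHLM (0.055), AT1G59660 (-0.071) and EXPA8 (0.025). For the interaction it turned in the light reaction list (0.13), the chlorophyll list (0.38), BGLU45 (-0.30), AT4G23680 (-0.26), SAG29 (-0.027), AT5G10120 (-0.19), AT5G39520 (-0.0030), AT1G13650 (0.37), AT5G48490 (0.63), STOMAGEN (0.16), AT5G52810 (-0.040), BZIP28 (-0.14), SIM (-0.018), BIK1 (-0.052), LHCB4.2 (0.17), PSBY (0.15), PSAN (0.17), ATPC1 (0.17), SBPASE (0.14), PRK (0.040), CHLM (0.17), HEME1 (0.18), AT1G59660 (-0.17), EXPA8 (0.39), GI (-0.0061) and AT1G22690 (0.24). For the genotypes after dexamethasone it turned in the light reaction list (0.10), the chlorophyll list (0.059), BGLU45 (-0.13), AT4G23680 (-0.19), AT1G13650 (0.10), AT5G52810 (-0.075), BZIP28 (-0.055), BZIP60 (-0.030), BIK1 (-0.025), LHCB4.2 (0.11), PSAN (0.16), PSBY (0.19), ATPC1 (0.11), SBPASE (0.10), PRK (0.044) and AT1G59660 (-0.020). Under spike scaling it turned for dexamethasone in CPR5-C plants in HSA32 (0.15), ATPC1 (0.045), PRK (0.023), RCA (0.34), AT3G14120 (0.15), GH3.3 (0.35) and FMA (0.13). The means of lists without a call turned there too, in the Calvin cycle (0.052), chlorophyll synthesis (0.060), heat shock (0.16) and oxidative stress (0.30). For the interaction it turned in the light reaction list (0.14), THI2.1 (0.16), HSA32 (0.51), PSAN (0.0088), ATPC1 (0.23), PRK (0.17), RCA (0.50), HEME1 (0.31), GH3.3 (0.56) and FMA (0.24). Of the lists without a call, the means of the Calvin cycle (0.21), chlorophyll synthesis (0.53) and heat shock (0.21) turned as well. For the genotypes after dexamethasone it turned in the light reaction list (0.061), the chlorophyll list (0.15), ATERDJ3B (0.37), THI2.1 (0.16), HSA32 (0.33), ATPC1 (0.11), PRK (0.13), RCA (0.47), AT4G32910 (0.30), AT3G14120 (0.30), GH3.3 (0.48) and FMA (0.38). Without a call, the means of the Calvin cycle (0.15) and heat shock (0.39) lists turned too. Quantile normalization turned HEME1 in the interaction (0.14). PDF1.2, at -0.74 and -0.82 without CPR5-C dexamethasone replicate 3, ranged from -0.74 to 0.95 (interaction) and from -0.82 to 0.87 (genotypes after dexamethasone) with an array left out. In the simulation of centred values loess turned the sign of 952 of 2442 changes of at least 1 and quantile normalization of 4, so the loess turns say little of these genes. The spike turns follow from the constant added (0.41, 0.58 and 0.52). For HEME1 under quantile normalization and for PDF1.2 the cause was not tested.

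Not run were the filter on dim probe sets (the values hold no absolute level), a random block in camera (it takes none) and the mean of probe sets per locus (each list member had 1). The group-wise fit has no interaction. Signal over background is unknown here, so weak probe sets could not be set apart.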

Other observations

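All tests in this part were chosen after the data were seen, except the spike and labelling tests of the plastid genes, which were set down before their results.

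Among 189 gene families and description words tested for enrichment, the cold-regulated COR family was over-represented among the genes at least 1 higher in CPR5-C plants after dexamethasone, with 3 of 4 members (Fisher's exact test, adjusted p = 0.0404). COR15B (4.96, SE 0.09) stood beside COR15A and COR47. Genes described as dehydrogenases were over-represented too, with 7 of 32 (Fisher's exact test, adjusted p = 0.0404). These were the aldehyde dehydrogenases ALDH7B4 (4.38, SE 0.10), ALDH10A9 (1.23) and ALDH10A8 (1.11), the alternative NADH dehydrogenase NDB2 (1.93), AT4G33150 (1.66), FDH (1.57) and SDH2-1 (1.2, with another probe set at 0.14). COR15B and these enzymes were named after their values were seen. The median of the 4 COR genes was 4.04 as deposited and 0.29 under cyclic loess, where 2 were called higher. Cyclic loess removed most of each large change in the simulation of centred values, so this fall says little of these genes.

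In wild-type plants the genes lower after dexamethasone held 4 of 9 plant U-box ligases, PUB23 (-1.07), PUB22 (-0.58), PUB25 (-0.34) and PUB26 (-0.29) (Fisher's exact test, adjusted p = 0.0181), while 3 other members were higher. The word plant was over-represented through the same genes (adjusted p = 0.0457, Fisher's exact test). Expansin-like genes were over-represented with 3 of 5 (Fisher's exact test, adjusted p = 0.0289): EXLA1, EXLA2 (-1.40) and EXLA3 (-0.44). The same 3 were lower in CPR5-C than in wild-type plants after water (Fisher's exact test, adjusted p = 0.0296), with EXLA2 at -1.39 and EXLA3 at -0.39. Of the plant U-box ligases 0 were called lower in that comparison and 2 higher.

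In CPR5-C plants after dexamethasone 50 of 69 plastid probe sets were lower and 16 of 23 mitochondrial ones higher (camera with an estimated correlation, p = 0.107 and p = 0.0448), and 2 technical explanations were weighed. The first was a change in how organelle RNA, which lacks nuclear poly-A tails, is labelled. A change common to both organelles is argued against by the mitochondrial median of 0.71 (bootstrap SE 0.19), since these transcripts would have had to fall too. That median was 0.33 with quantile normalization and 0.0070 with cyclic loess. A labelling change that differs between the organelles was not tested and stays open. A global shift that scaling divides out stays open for the plastid genes: scaled to the spikes their median was -0.20 (bootstrap SE 0.06 over probe sets), which met the bound set beforehand against it, but between arrays the difference was -0.11 ± 0.16 (SE), and this spread was added after that value was seen. A lower plastid transcript level in induced plants may be biological, as a hypothesis only. The plastid interaction had 28 of 69 probe sets negative as deposited (median -0.40), and 4 negative and 11 positive with spikes (0.18). Under quantile normalization and cyclic loess 0 were called negative (-0.092 and -0.0047). The mitochondrial median was 0.78 as deposited, 1.37 with spikes, 0.51 with quantile normalization and 0.097 with cyclic loess. On simulated centred values, quantile normalization returned a median of 50.0% and cyclic loess 4.30% of each change of at least 1. A fall toward 0 under these 2 therefore cannot show whether the organelle changes depend on the scaling.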
